A study of Ipomoea batatas and Ipomoea carnea with 7 samples.

How the data were processed

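Sweet potato leaf, fibrous root and tuberous root at ambient temperature and after heat, and I. carnea fibrous root at ambient temperature, made 7 groups with 1 array each. Groups were taken from the labels. Per the labels, plants were kept at 30 ± 2 °C by day and 23 ± 1 °C by night, the heat set was held at 40 ± 2 °C for 7 hours daily over 7 days from an age of 21 days, 30 plants made a set, and tissue was harvested at 30 days. The wording on which set served as control is unclear, and pooling of RNA over plants is not stated. The labels spell the wild species both carnea and cornea. Per the labels' protocols, 500 ng of total RNA was amplified from an oligo-dT primer and labelled with Cy3.

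Per the file headers, the authors read the arrays with Agilent Feature Extraction 10.7.3.1, which gives for each spot a background-subtracted and detrended signal on a linear intensity scale, its error and flags for signal well above background, saturation and outliers. All 7 arrays lay on 1 slide, and 6 were read in a first scan and 1, heat tuberous root, in a second. The deposited series table holds log2 values. For at least 99.3% of the probes of each array they equalled the log2 processed intensity minus a constant near the 75th percentile of the array (within 0.001), so scale and direction are known, and the tool behind the scaling is not given in the sources used here. The medians of its columns were -3.03, -2.93, -3.05, -2.72, -2.95, -2.66 and -2.39 in the order of the groups above.

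Control spots and spots marked as outliers were left out (a probe with no other spot kept its own), and spots of 1 probe were averaged on the log2 scale, from 61657 spots to 56510 probes. Probes spotted 2 times (5147) gave a robust SD between spots of 0.0635 to 0.123 (log2), and 0.350% to 3.46% of the pairs well above background were at least 2-fold apart. No probe was saturated. Each array was scaled by its 75th percentile. A rule fixed before the data were examined took the percentile over probes well above background on all 7 arrays if most probes of any array were not. The heat tuberous root array met that condition, so the 18024 probes well above background on all 7 arrays were used. None of the 54757 sequence identifiers matched the reference table of gene names, and no genome was used, so genes carry the names and identifiers of the array's annotation, and no genome positions are given.

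For comparisons of 2 arrays, a probe entered if well above background on at least 1. Where it was not so on the dimmer array, that side was set to the higher of its own value and the lowest signal well above background there, giving a bound ("at least"). No fold is given where both sides were below. Probes at least 2-fold apart were counted, with no p-value. In organ comparisons the same floor, set on each array of the dimmer side that was not well above background, gave bounds from the means of each side. The limma and camera fits used the scaled signal of every array, dim ones included, so their fitted sizes are not bounds. Gene lists (41) were fixed before the data were examined and matched to annotation texts by pattern, with 1 probe per text, the brightest over the 6 sweet potato arrays. Of these, 27 had members. Members are annotation entries, and several entries can belong to 1 gene. The random lists below were drawn probe by probe, so their percentiles take no account of members that move together. The median log2 difference of each list with at least 3 compared members was placed among 10000 random lists of the same size, matched on mean signal in 20 bins. On simulated lists of 20 probes in the leaf comparison, 50 of 50 lists shifted by 1 log2 unit and 5 of 50 unshifted lists fell outside the central 95%.

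Heat across organs and organs across temperatures were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend, two-sided, Benjamini-Hochberg, adjusted p 0.05) on the 39798 probes well above background on at least 3 of the 6 sweet potato arrays. The organ, or the temperature for organ contrasts, was a block, leaving 2 residual degrees of freedom, with a median prior of 5.54. Nothing says that arrays of different organs are replicates, so these p-values measure the spread between these arrays only. Lists with at least 5 tested members (10) were tested with camera at a preset correlation of 0.01, and again with an estimated one.

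The limma step was tested on simulated data with 200 changed probes among 39798, and its noise model was revised after the first output was seen. All 3 forms are given, since they differ. In the heat comparison, with noise from the variances of the fit, 15.0% of 4-fold and 96.0% of 16-fold changes were recovered, and 19 of 130 calls were of unchanged probes. With variances drawn from the fitted prior, 0 of 100 and 16 of 100 were recovered, and 3 of 19 calls were of unchanged probes. With the same noise and 50 changes each of 4-fold, 16-fold, 64-fold and 256-fold, 0, 20, 44 and 49 were recovered, with 7 of 120 calls of unchanged probes. In the leaf contrast the first form recovered 11.0% and 88.0%, with 17 of 116 calls of unchanged probes, the second 0 and 0 of 100, with its 1 call of an unchanged probe, and the third 1, 14, 44 and 50 of 50, with 12 of 121. What the design can detect at 16-fold thus depends on the assumed noise, and the share of wrong calls was over 5% in each form.

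Named genes followed a rule fixed before the data were examined. In each organ these were the 8 largest differences each way with signal on both arrays that kept direction under the scalings. Across organs they were the 12 largest each way past the test, filled with genes at least 2-fold apart the same way in all 3 organs. The rule added up to 4 members per list, the 6 largest each way past the test for each organ, and the 6 largest each way for I. carnea. Alternatives were 75th percentile scaling over the probes well above background on the arrays compared, median scaling (over the probes well above background on all arrays), quantile normalization, normexp with an offset of 50 on the median signal (1 of the 7 files holds a mean signal), the deposited log2 table, other filters on dim probes, a 4-fold threshold, fits without trend or block, and each organ left out in turn. Scaling over all probes, a common floor and fits without the heat tuberous root array were chosen after seeing the data. The common floor was revised once: applied to all tested probes it left probes with no variance and gave no calls, so it was then limited to probes above the floor on at least 3 arrays. Figures were drawn with matplotlib 3.10.9, and Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6 was used for the rest.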

Results

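Transcript levels were measured in sweet potato (Ipomoea batatas, variety Sree Arun) grown at ambient temperature or exposed to daily heat, and in the fibrous root of a wild relative, Ipomoea carnea, at ambient temperature. Young leaves, fibrous roots and tuber-forming roots (tuberous root below) were taken from plants 30 days old. By the labels, the 7 days of heat began at an age of 21 days, so harvest may have followed the last heat exposure. Differences called "in heat" below are those of the heat set against the ambient set. Each of the 7 groups was represented by 1 one-colour array, so a difference between 2 arrays carries no replicate check, and the number of arrays limits the precision throughout. Whether the RNA of an array came from 1 plant or from several of the 30 plants of a set is not stated in the sources used here.

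The arrays carried 56510 probes for sweet potato sequences. Of these, 414 probes were annotated with 251 named messenger RNA entries, and the rest with unnamed assembled contigs, so the named genes below cover 0.733% of the probes. Genes are counted below as entries, and several entries can belong to 1 gene, as with chalcone isomerase. Many probe names hold the mark Xhyb, which may stand for cross-hybridisation, so a value can come in part from a related sequence. Except for 1 chaperonin, no heat shock protein or heat shock factor was among the named entries. The share of probes well above background was 67.9% in ambient leaf, 75.9% in heat leaf, 66.3% in ambient fibrous root, 67.3% in heat fibrous root, 69.99% in ambient tuberous root, 42.9% in heat tuberous root and 55.8% in I. carnea. The heat tuberous root array was also the only one read in a second scan of the same slide, so that scan cannot be told apart from its group. Its 75th percentile signal was 48.0, against 233 on the ambient tuberous root array.

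**Figure D1:**
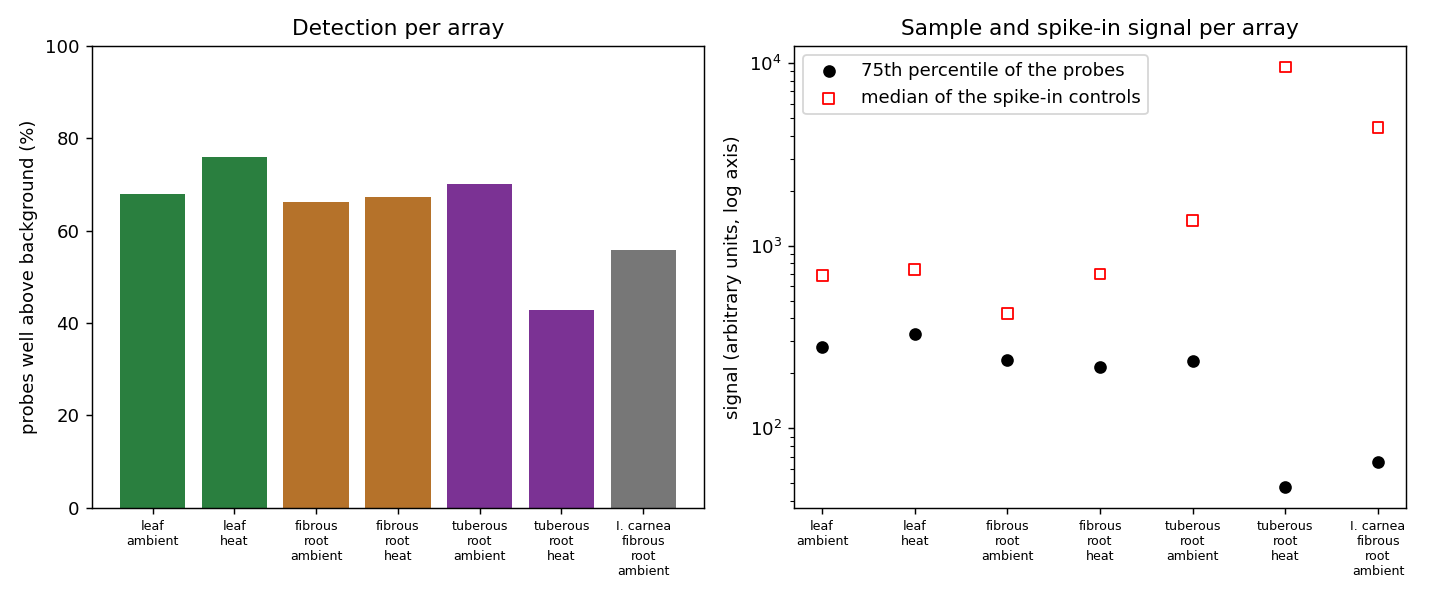
The left panel gives the percentage of probes well above background on each of the 7 arrays, and the right panel the 75th percentile of the probe signal (filled circles) and the median signal of the spike-in controls (open squares) on a log axis. The heat tuberous root array has the lowest share of detected probes, 42.9%, and the highest spike-in median, 9528.

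The first question was how transcript levels in the leaf differed after 7 days of heat, 7 hours daily at 40 °C. Genes of starch synthesis stood higher in the heat leaf, with 11 of 17 list members at least 2-fold higher and 0 at least 2-fold lower. The secretory peroxidases, enzymes released to the cell wall, were higher too, 7 of 13 by at least 2-fold and 0 lower by as much, while genes of flavonoid and anthocyanin synthesis were lower, 18 of 23 by at least 2-fold. Among named genes with signal on both leaf arrays, the largest difference was that of the anionic peroxidase swpb2 (AY206413), at 61.2-fold higher in heat. Its ambient leaf signal was 23.6, where the lowest signal well above background was 10.4.

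Among the peroxidases, swpa4 (AY206409) was 17.5-fold (from an ambient signal of 16.5), swpb1 (AY206412) 10.5-fold and swpa2 (AF109124) 9.54-fold higher in the heat leaf. A proline-rich protein (EF192429) was 20.01-fold and the metallothionein-like protein SPMT (AF242374), of a family of metal-binding proteins, 12.9-fold higher. IbF6H1-1 (AB636149), annotated as an oxidoreductase, was 7.79-fold higher and the sucrose transporter SUT2y (GU395494) 7.63-fold. In the starch list, the small subunit of ADP-glucose pyrophosphorylase (X83498), part of the enzyme that makes the glucose donor for starch, was 4.03-fold higher, and the large subunit entries AJ252316 and AF068260 were 6.60-fold and 5.64-fold higher. The median log2 difference of the starch list was 1.77, higher than that of all 10000 random lists matched on signal (percentile 100). The peroxidase list had a median of 1.27 (percentile 99.9) and the lignin and phenylpropanoid list a median of 1.15 (percentile 99.6), with 4 of 6 members at least 2-fold higher, among them phenylalanine ammonia-lyase (M29232) at 2.33-fold.

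On the lower side, the transcription factor swDREB1 (EF433457) had a log2 difference of -3.15, dihydroflavonol reductase DFR-A (AB112668) one of -2.76, the flavonoid glucosyltransferase uf3gt (AB038248) one of -2.42, cyclin D3 CycD3;2 (AB478417) one of -2.31 and chalcone isomerase (AB037396) one of -2.26. Anthocyanidin synthase (GU598212) had -2.07, and the sporamin A entries DQ195762 and DQ195776 had -2.12 and -2.11. The flavonoid list had a median of -1.41 and the list of sporamin and storage proteins (sporamin list below, which also holds a Kunitz-type trypsin inhibitor and ipomoelin), with 12 of 14 members at least 2-fold lower, one of -1.55, both below all matched random lists (percentile 0). Lists within the central 95% of random lists were the antioxidant enzymes (median -0.000460, percentile 71.0), sucrose metabolism and transport (0.66, 94.1), carotenoid synthesis (-0.14, 43.7), MADS and homeobox factors (-0.24, 8.69) and the retrotransposons (0.83, 97.4).

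Over all probes, 8944 were at least 2-fold higher and 3787 at least 2-fold lower of 44034 compared, so 70.3% of the differences pointed up. That balance depends on the scaling: 48.8% pointed up with the 75th percentile over all probes, 54.3% with the median, 49.1% with quantile normalization and 48.8% in the deposited log2 table. The median over the 37205 probes well above background on both leaf arrays, 0.16, moved by -0.32, -0.24, -0.30 and -0.32 under these, and by -0.15 with the percentile over probes well above background on the arrays compared.

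In the fibrous root, the storage protein sporamin was far lower in heat. Of 20 list members compared, 18 were at least 2-fold lower, and 0 were higher by as much. Entries of starch synthesis were lower as well, 14 of 17 by at least 2-fold, together with 16 of 19 flavonoid entries and 5 of 5 carotenoid entries. Higher in heat were the oxidoreductase entries IbF6H2-2-1 (AB636152), at 82.3-fold, and IbF6H2-1-8 (AB636154), at 50.3-fold. Both probes hold the mark Xhyb, and the probe of AB636152 is named for AB636154. These entries may therefore not be separate measurements.

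The sporamin B entry DQ195758 had a signal of 51877 in the ambient fibrous root and of 19.9 in the heat one, a log2 difference of -11.23. Only 3 of the 20 members, with a median of -1.41, were well above background on both arrays, and the bounds of the others reached at least 7211-fold lower (DQ195762). The sporamin entries are close copies of one another, so their probes are not separate measurements. The proteinase inhibitor SPLTI-b (AF404833) had a log2 difference of -5.60, the pyrophosphorylase entries X83498, AJ252316, Z79635 and AB271014 differences of -4.74, -4.74, -4.72 and -4.51, and the flavanone hydroxylase entries EF108572 and AB023790 differences of -4.69 and -4.64. The list medians were -11.30 for sporamin, -2.42 for starch synthesis and -3.19 for flavonoids, all at percentile 0, and -1.70 for carotenoids at percentile 0.275. Of 19 flavonoid members, 10 were well above background on both arrays, with a median of -1.84, so the -3.19 rests partly on bounds.

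Besides the IbF6H2 entries, the reverse transcriptases of the retrotransposons Tib1 (AF223309) and Tib6 (AF223314) were 32.4-fold and 17.1-fold higher in the heat fibrous root, and cinnamate 4-hydroxylase (GQ373157), an early enzyme of the phenylpropanoid pathway, 12.3-fold. The sucrose transporter SUT1y (GU120194) was 6.61-fold, polyphenol oxidase I (AB038994) 5.23-fold and a catechol oxidase (AJ245880) 5.15-fold higher. Inside the central 95% of random lists lay the antioxidant enzymes (median -0.45, percentile 9.38), the peroxidases (-0.19, 22.7), sucrose metabolism and transport (0.07, 54.6), lignin and phenylpropanoids (0.51, 87.1), MADS and homeobox factors (0.09, 49.3) and the retrotransposons (0.79, 94.9). Over all probes, 9065 were at least 2-fold higher and 6351 at least 2-fold lower of 41382 compared, with 58.8% pointing up. Quantile normalization turned that balance, with 7276 higher and 7501 lower (49.2% up), and moved the median over the 34130 probes well above background on both arrays by -0.16.

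In the tuberous root, sporamin was again far lower in heat, in 18 of 20 members compared and by a median log2 difference of -6.61. Starch synthesis was lower in 15 of 17 members (median -3.00) and flavonoid synthesis in 17 of 21 (median -2.57), all 3 lists at percentile 0. The retrotransposons were higher, 8 of 12 members by at least 2-fold, with a median of 2.54 at percentile 99.99. The count lower by as much was 0, but for 10 of the 12 the ambient level lay below the detection floor of the heat array. In those members a fall could not be seen. IbF6H2-1-8 and IbF6H2-2-1 were 239-fold and 82.6-fold higher. Their ambient signals, 9.29 and 13.3, lay near the lowest signal well above background on that array, 8.90, so the size of these folds is uncertain.

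The 8 largest differences on the lower side among named genes with signal on both arrays were all of sporamin entries, from -9.35 (DQ195759) to -6.97 (EU250004). Starch synthesis on this side included AB271014 at -5.94 and X83498 at -3.72, while the subunit IbAGPb3 (AB271016) stood 2.93-fold higher. Carotenoid genes had a median of -1.81 (percentile 0.400) and zeaxanthin epoxidase (HQ828089) a difference of -3.15. The peroxidase list, higher in the heat leaf, had a median of -1.64 in tuberous root (percentile 0.0900), with swpa2 at -4.64, swpa3 (AF109123) at -4.23 and swpb2 at -3.39, but swpa7 (EF433454) had a difference of 3.42. Also higher were SUT1x (GQ979977) at 12.3-fold, the JA-domain protein IbJ8 (AB246796) at 9.98-fold, cinnamate 4-hydroxylase at 9.57-fold, Tib1 at 8.40-fold and the DNA-binding protein SPF1 (D30038) at 7.78-fold. The antioxidant enzymes (median -0.19), sucrose metabolism and transport (-0.37, 21.2), lignin and phenylpropanoids (0.28, 55.2) and MADS and homeobox factors (-0.14, 21.0) lay within the central 95% of random lists.

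Over all probes, 8263 were at least 2-fold higher and 7386 at least 2-fold lower in the heat tuberous root of 40267 compared, with 52.8% pointing up. That share was 63.2% with the 75th percentile over all probes, 63.5% with the median, 78.8% with normexp and 63.2% in the deposited log2 table, and these settings moved the median over the 23516 probes well above background on both arrays by 0.30, 0.31, 0.49 and 0.30.

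**Figure D2:**
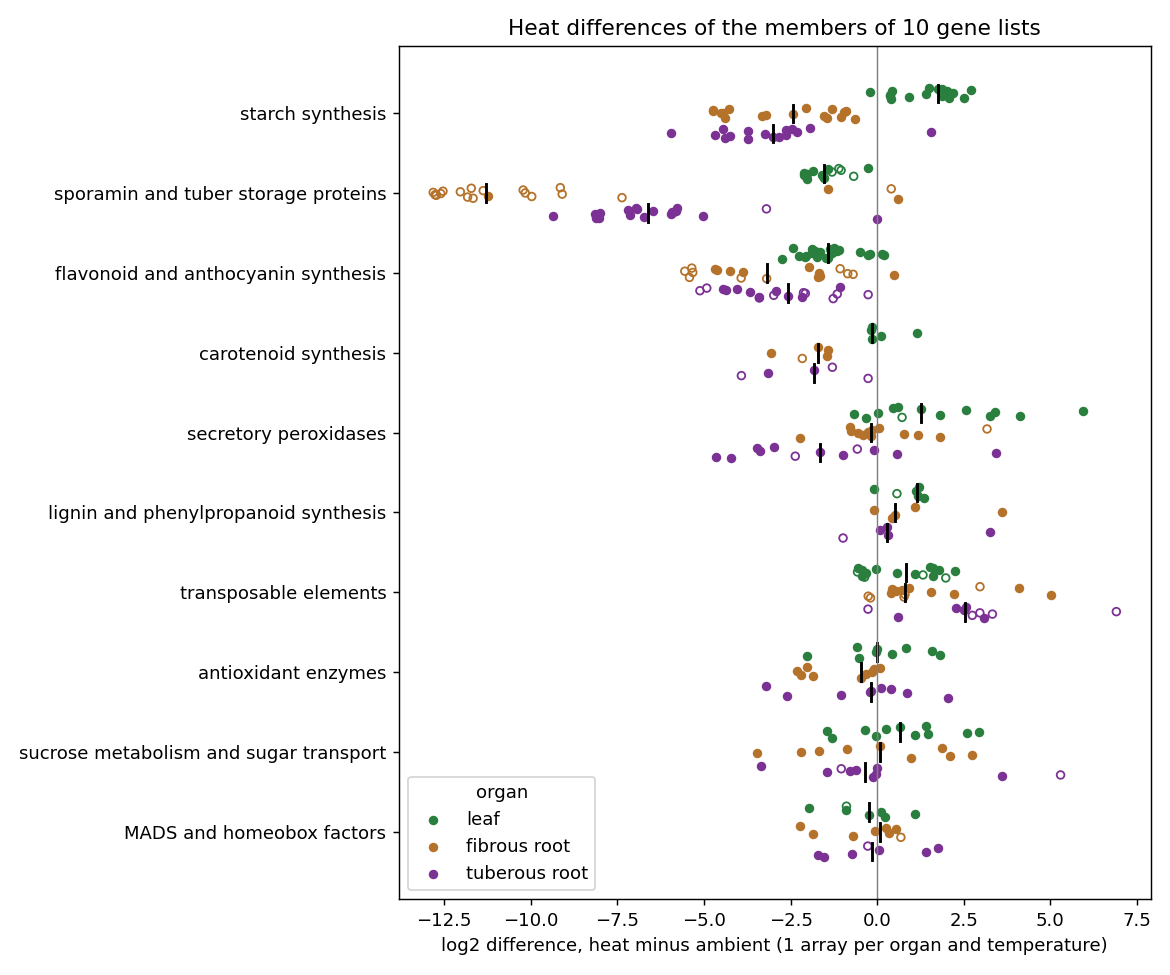
Each point is 1 member of a gene list fixed beforehand, placed by its log2 difference of heat minus ambient (x axis) in leaf (green), fibrous root (brown) or tuberous root (purple), with 1 array per organ and temperature. Hollow points are bounds, where 1 of the arrays was not well above background, and black bars are list medians. Members whose bound turned the sign are not drawn but enter the medians as 0. The median of starch synthesis lies right of 0 in leaf (1.77) and left of it in fibrous root (-2.42) and tuberous root (-3.00). The median of the sporamin list lies left of 0 in all 3 organs. Single members can lie on the other side, as does the Kunitz-type trypsin inhibitor of that list in fibrous root (0.61).

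Probes with a like heat difference in all 3 organs were then sought, with the organs taking the place of replicates. By limma with the organ as a block, 0 of 39798 probes passed an adjusted p of 0.05, and 5823 had an unadjusted p under 0.05. The smallest adjusted p among named genes was that of IbF6H2-2-1, whose log2 difference was 6.37 ± 0.49 (SE, 3 organs) with a limma adjusted p of 0.0605. It was at least 50.1-fold higher in leaf, 82.3-fold in fibrous root and 82.6-fold in tuberous root. The spread in this test is that between organs and not between plants.

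The count of 0 moved with the organs and with the processing. Leaving out the leaf, limma called 1268 probes, 477 higher and 791 lower, without the fibrous root 157, and without the tuberous root 0. It called 47 with the 75th percentile over all probes, 32 with the median, 32 in the deposited log2 table, 2340 with normexp, 22 among probes well above background on every array and 165 with no filter on dim probes. It called 0 with quantile normalization, without the variance trend (5582 at an unadjusted p under 0.05) and without the organ block (2409).

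At least 2-fold higher in all 3 organs were 9 named genes, and 30 were at least 2-fold lower in all 3. The higher ones were IbF6H2-2-1, IbF6H2-1-8, the sucrose transporters SUT1x and SUT1y, cinnamate 4-hydroxylase, the glutathione S-transferase GST1 (EU563267) and the retrotransposons Tib1, Tib2 (AF223310) and Tib9 (AF223317). For the IbF6H2 and Tib entries the ambient tuberous root level lay below the detection floor of the heat array. For IbF6H2-2-1 and IbF6H2-1-8 it was -7.09 and -7.62 (log2), against a floor of -5.43. In that organ a fall of these entries could not be seen, so their agreement there is weak evidence. GST1, of a family that conjugates toxic compounds, was 4.28-fold, 3.38-fold and 6.38-fold higher in leaf, fibrous root and tuberous root, with a limma unadjusted p of 0.00143 and an adjusted p of 0.158. Ranked by the smallest of their 3 organ differences, the first 12 on the lower side were ascorbate peroxidase (AY206407), which removes hydrogen peroxide, 3 chalcone isomerase entries, chalcone synthase (FJ478180), anthocyanidin synthase (FJ478179), 2 dihydroflavonol reductase entries (EU402466, AB019243) and 4 sporamin A entries. Ascorbate peroxidase had log2 differences of -2.02, -1.87 and -2.61, with a limma unadjusted p of 0.000703 and an adjusted p of 0.158.

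As groups across the 3 organs, sporamin (median log2 difference -7.48, 19 members), flavonoid synthesis (-2.35, 21 members), starch synthesis (-1.29, 17 members) and carotenoid synthesis (-1.80, 5 members) shifted down against other probes, and the retrotransposons (1.30, 13 members) shifted up. The adjusted p by camera with a preset correlation of 0.01 was 3.55e-17, 8.76e-17, 1.20e-04, 0.00118 and 0.00397. With an estimated correlation none of the 5 calls held, with a camera p of 0.120 for sporamin, 0.0694 for flavonoids, 0.343 for starch, 0.231 for carotenoids and 0.208 for the retrotransposons, and adjusted p of 0.469 (0.490 for starch). That correlation was 0.85 for carotenoids, 0.75 for starch, 0.67 for sporamin, 0.29 for flavonoids and 0.18 for the retrotransposons. Starch synthesis was called down although 11 of its 17 members were at least 2-fold higher in the leaf. Its median was -2.92 without the leaf, -0.62 without the fibrous root and -0.58 without the tuberous root. The sporamin median was -4.17 without the fibrous root, and the carotenoid median -2.76 without the leaf and -0.92 without the tuberous root. Without the tuberous root, the retrotransposon call ended (adjusted p 0.110), with a median of 1.26 and a mean of 0.84 against 1.30 and 1.33 with all organs. Without the leaf, the peroxidases, with a median of 0.50, a mean of 0.11 and an adjusted p of 0.998 across the 3 organs, shifted down with an adjusted p of 0.0359. The sucrose list had a median of -0.27 and a mean of 0.33, of opposite signs, with a direction of down by camera (adjusted p 0.922).

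Counts of list members at an adjusted p under 0.05 by limma were 0 over all probes. Adjusted over the list alone, 18 of 19 members of the sporamin and storage protein list, 16 of 21 flavonoid genes, 3 of 13 retrotransposons, 2 of 9 antioxidant enzymes and 2 of 2 cell cycle genes passed. Except for the retrotransposons (5 unadjusted), these counts equal those at an unadjusted limma p under 0.05, so this adjustment removed no member there. The cell cycle genes were the cyclins D3 CycD3;1 (AB478416) and CycD3;2, with mean log2 differences of -1.98 and -1.76. In the lignin list 1 of 5 passed, cinnamate 4-hydroxylase, and 0 of 17 starch synthesis genes did. Lists with 1 tested member are not counted here, since adjusting over them changes nothing.

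Lists with fewer than 3 members gave single values in leaf, fibrous root and tuberous root. 1-aminocyclopropane-1-carboxylate oxidase (GU230145), which makes ethylene, had log2 differences of 1.44, -1.63 and -4.88. The transcription factors WRKY1 (GQ280386) and NAC1 (GQ280387) had 1.80, 0.49 and 0.51, and 1.46, -0.36 and 1.49. The late embryogenesis abundant protein LEA14 (GU369820) had 0.25, 0.19 and 2.17, with the leaf value below 0 under some scalings. The chaperonin subunit (DQ016992) had -0.55, -0.46 and 0.01, the last of either sign by scaling. Of genes often taken as references, actin (AY905538) had -0.35, 0.27 and 0.29, the last also of either sign, and cyclophilin (EF192427) had 0.66, -0.62 and -2.46.

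The heat differences of the organs overlapped. Of 36143 probes compared in all 3, 1152 were at least 2-fold higher in each organ, where independent lists would share 339, and 870 were at least 2-fold lower in each, where independent lists would share 105. Opposite differences between fibrous and tuberous root were seen for 1008 probes, against 2855 for independent lists. Across the 21796 probes well above background on all 6 sweet potato arrays, the heat differences correlated at r = 0.48 between fibrous and tuberous root, 0.33 between leaf and fibrous root and 0.24 between leaf and tuberous root. Probes are not independent replicates, and no p-value is given for these correlations.

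The organs were compared over both temperatures, each with the mean of the other 2. A gene above or below that mean need not differ alike from each of them. In the leaf, rubisco activase (EU287993), which keeps the carbon-fixing enzyme active, was above the other organs by a log2 difference of 10.84 ± 0.59 (SE; limma adjusted p 0.000628). The pyrophosphorylase subunit IbAGPb3 was 217-fold above (adjusted p 0.00132). ADP-glucose pyrophosphorylase large subunit 4 (JQ797695) was at least 193-fold above (0.000880), lycopene epsilon cyclase (HQ828093) at least 207-fold (0.00156), dihydroflavonol reductase (AB019243) at least 98.6-fold (0.00637) and a glucosyltransferase (EF108571) at least 222-fold (0.00136). These last 4 genes were well above background on 3, 2, 2 and 1 of the 4 root arrays, in the order given. On the lower side, the homeobox gene Ibkn3 (AB283029) was at least 74.9-fold below the roots (adjusted p 0.000880), and 5 sporamin entries were below, such as DQ195758 by at least 724-fold (adjusted p 0.0112; above background on 1 of 2 leaf arrays). In all, 2125 probes were above and 2177 below by limma at an adjusted p of 0.05, and without the temperature block 2269 were called.

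In the fibrous root, IbF6H2-1-8 and IbF6H2-2-1 were at least 61.9-fold and 66.2-fold above the other organs (limma adjusted p 0.0269 and 0.0195; above background on 3 of the 4 other arrays), and the MADS-box gene AGL17 (DQ011557) was above their mean by a log2 difference of 3.33 ± 0.53 (0.0326). Only the leaf made AGL17 stand out, since its level in fibrous root lay under that in tuberous root at both temperatures. Below were 3 anthocyanidin synthase entries (AB023787, EF187730 and FJ478179) by at least 48.2-fold, 23.3-fold and 38.7-fold (adjusted p 0.0313, 0.0357 and 0.0287), each above background on 1 of the 2 fibrous root arrays. The glucosyltransferase EF108571, the acid invertase Ib2FRUCT3 (AY037938) and uf3gt were at least 36.3-fold, 32.0-fold and 8.21-fold below (adjusted p 0.0228, 0.0253 and 0.0299). In all, 321 probes were above and 432 below, and without the temperature block limma called 1.

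In the tuberous root, the homeobox genes Ibkn2 (AB283028) and Ibkn3 were 44.4-fold and at least 22.5-fold above the other organs (limma adjusted p 0.0234 and 0.0283; Ibkn3 above background on 2 of the 4 other arrays), MADS1 (AF396746) 39.2-fold (0.0359) and AGL17 19.6-fold (0.0311). Class I knotted-like homeobox proteins such as Ibkn2 are regulators of meristem identity. A proline-rich protein (EF192429) was 41.2-fold (0.0452) and the metallothionein-like MT2 (AF177760) 18.1-fold above (0.0317). Rubisco activase and the peroxidase swpa6 (AY206411) were below by -5.94 and -4.27 (limma adjusted p 0.0247 and 0.0325), and ADP-glucose pyrophosphorylase large subunit 4, above background on 1 of 2 tuberous root arrays, by at least 10.1-fold (0.0416). For some of these genes the leaf lay far from both roots. Rubisco activase had a mean level (log2) of 5.24 in leaf and -5.60 over the roots. MADS1, ambient and heat, stood at 4.28 and 6.03 in tuberous root, 3.57 and 3.82 in fibrous root and -2.99 and -4.96 in leaf. Large subunit 4 stood at -6.65 and -7.28 in fibrous root as well. By contrast, swpa6 was lower in tuberous root (-4.81 and -4.22) than in fibrous root (-1.10 and -0.31) and leaf (0.56 and -0.11). The totals were 122 above and 118 below. They depended on the fit: without the temperature block limma called 0 (4498 at an unadjusted p under 0.05) and without the variance trend 0 (6373), while normexp gave 2257 above and 669 below. A fit without the dim heat array leaves 1 tuberous root array, so it cannot show whether the calls rest on that array being dim.

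The last comparison set the fibrous root of I. carnea against that of sweet potato at ambient temperature. Counted after the values were seen, 15 of 19 members of the sporamin and storage protein list were at least 2-fold lower in I. carnea and 0 higher by as much, while the sporamin entry U17336 was 1.63-fold higher. Flavonoid genes went both ways, 12 of 21 at least 2-fold higher and 8 lower by as much, among the latter dihydroflavonol reductase EU402466 (at least 24.5-fold) and flavanone hydroxylase EF108572 (11.4-fold). Sporamin entries DQ195760 and DQ195764 had log2 differences of -10.00 and -9.70, and MADS1 one of -9.11. Chalcone synthase entries CHS-LF4 (AB037390) and CHS-LF3 (AB037389) were 72.8-fold and 67.9-fold higher, anthocyanidin synthase EF187730 71.3-fold, CycD3;2 41.2-fold, expansin 2 (EU581634), of a family that loosens cell walls, 32.0-fold and a cysteine proteinase-like gene (AF242185) 31.2-fold.

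The probes were designed for sweet potato, so a dim signal in I. carnea can come from mismatch. Its array also had a 75th percentile signal of 65.6 and a spike-in median of 4457, against 237 and 425 for ambient fibrous root of sweet potato, a low sample signal beside bright spike-ins as on the heat tuberous root array. Probes of like genes disagreed: the granule-bound starch synthase entry AB071604 had a log2 difference of 3.12, while AB524728 was at least 234-fold lower. Of 40915 probes compared, 15510 were at least 2-fold higher and 9364 at least 2-fold lower, with 62.4% pointing up, or 77.2% with normexp. The median over the 28093 probes well above background on both arrays, 0.73, moved by 0.38 with the 75th percentile over all probes, 0.37 in the deposited log2 table, 0.31 with normexp and 0.19 with the median.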

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

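Of the tests below, the one for tuberous root tissue in the ambient fibrous root sample was fixed before its result was seen, and the others (dim array, raised floor, genomic DNA, scanner gain, amount of labelled RNA and regroupings of the arrays) were chosen after the results were seen.

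Given here are genes under the naming rule whose heat difference went opposite ways in 2 organs by at least 2-fold, with signal on all 4 arrays. Lists outside the central 95% of random lists on opposite sides are given too. Each value is the difference between organs (log2), for genes the pair of organs farthest apart. Entries outside the rule can meet these limits too, such as the granule-bound starch synthase AB071604 (2.09 in leaf, -4.39 in tuberous root). None of these differences between organs was tested, since each rests on 1 array per organ and temperature. Leaf minus fibrous root was 4.19 for the starch synthesis median, 6.90, 7.46, 6.75 and 6.75 for the ADP-glucose pyrophosphorylase entries AF068260, AJ252316, X83498 and Z79635, 6.06 and 5.12 for the sucrose transporters SUT2x (GQ979979) and SUT2y, 4.03 and 3.92 for the catalases GU230147 and X05549, which break down hydrogen peroxide, and 2.60 for the ubiquitin-conjugating enzyme-like SRF3 (AB125882). Leaf minus tuberous root was 4.76 for the starch median, 8.13 for AB271014, 2.91 for the secretory peroxidase median, 9.33, 7.89 and 5.04 for the peroxidases swpb2, swpa2 and swpb1, 6.32 for 1-aminocyclopropane-1-carboxylate oxidase, 4.47 for IbF6H1-1, 4.30 for zeaxanthin epoxidase and -3.71 for MADS1. Fibrous minus tuberous root was 4.39 for catechol oxidase (AJ245880) and 4.43 for polyphenol oxidase I. The spike-in controls, which no comparison uses, had a median signal of 9528 on the heat tuberous root array, against 425 to 4457 on the others.

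Sporamin and other storage protein probes were far dimmer in heat in both roots. The dim heat tuberous root array cannot account for the fall in the fibrous root, whose heat array was not dim. There the list also lay at percentile 0 of matched random lists. This does not show how far the dim array adds to the fall in the tuberous root. In that organ 18 of 20 members were well above background on both arrays, with a median log2 difference of -6.84. Sporamin was bright in the ambient fibrous root, so that sample may have held tuber-forming tissue. If so, the 196 other probes at least 16-fold higher in ambient tuberous root than in heat fibrous root and ambient leaf would stand near the sporamin share of their tuberous root level, 16.3%, and their median log2 distance from it was -1.05 (bootstrap 95% -1.23 to -0.89), with an upper limit within the 2-fold bound set for exclusion. Mixed tissue and a heat response therefore cannot be told apart in the fibrous root, and later storage root formation in the heat set also stays open as untested.

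Retrotransposon probes at least 2-fold brighter in heat were 8 of 16 in leaf and 5 of 14 in fibrous root, both lists within the central 95% of matched lists. On the heat tuberous root array they were 8 of 12. The raised detection floor of that array stays open as a cause there: of the 12 members compared, 2 had an ambient level at or above that floor and could be seen without being higher in heat, too few to decide (Tib11, AF223319, at 0.60, and Tib5, AF223313, with a bound of -0.27). Genomic DNA in the heat RNA could raise such probes, and the list lay above the central 95% of matched lists in the tuberous root only, with a lowest percentile of 94.9 (fibrous root), so it stays open too, beside a response of these elements to heat.

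The sample signal of the heat tuberous root array was low. A lower scanner gain by itself would dim the spike-in controls too, and they were 6.96 times as bright as on the ambient array. However, spike-in medians ranged from 425 to 4457 among the arrays of the first scan. They therefore do not gauge the gain, and a lower gain stays open. Less labelled sample RNA is a candidate explanation: the ratio of sample to spike-in signal was 0.0296 of that on the ambient array. The I. carnea array, read in the first scan, also had a low 75th percentile signal (65.6) beside bright spike-ins (4457). Mismatch to the probes can dim that array, so it does not settle whether the second scan played a part. Whether the amount of RNA or its quality underlies the low signal of the heat tuberous root array was not tested.

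Swapping heat and ambient within organs gives 4 splits, too few for a share under 0.05. All 4 gave 0 probes by limma (real 0, highest other 0), and 2 of the 4 gave at least as many lists by camera at the preset correlation as the real split (real 5, highest other 6). With no organ block, all 10 splits of the 6 arrays gave 0 probes (real 0, highest other 0), and 10 splits are too few as well.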

How the results depend on the processing

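Scaling over all probes, the common floor and fits without the heat tuberous root array were chosen after seeing the data, and the other alternatives were planned. No paired analysis was possible because each group holds 1 array, beyond the organ block of the heat fit, which sets heat against ambient within each organ. Unless a cause is given, the cause of a change was not tested.

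Between 2 arrays, a 4-fold threshold, which passes fewer probes by construction, gave 2405 higher and 793 lower in leaf, 2446 and 1839 in fibrous root, 4074 and 3163 in tuberous root, and 6567 and 6001 in I. carnea. Normexp gave 3832 and 2152 in leaf, 3795 and 3384 in fibrous root, 2855 lower in tuberous root and 5298 lower in I. carnea. In leaf, quantile normalization gave 5873 higher and 6077 lower, and 6302 were lower with scaling over all probes and 6295 in the deposited table. With no filter on dim probes, 22297 were higher and 11987 lower in tuberous root, and 26270 were higher in I. carnea. With probes well above background on both arrays, 5077 were lower in I. carnea.

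Across organs, limma called 0 probes for heat. It called 47 with scaling over all probes, 32 with the median, 2340 with normexp, 32 in the deposited table, 22 with probes well above background on every array and 165 with no filter. Leaving out 1 organ gave 0 (tuberous root) to 1268 (leaf), with 157 without the fibrous root. For leaf, 2269 of 4302 probes were called with no temperature block. For fibrous root the count of 753 became 1338 (scaling over all probes), 1298 (median), 4015 (normexp), 1303 (deposited table), 1701 (no filter), 376 (no trend) and 1 (no block). For tuberous root the count of 240 became 592, 557, 2926, 553 and 928 under the first 5 of these, and 0 with no trend and 0 with no block. No count is given for it without the heat tuberous root array, since that fit leaves 1 tuberous root array. The common floor, at the detection limit of the dimmest array and over 25644 probes, gave 0 for heat, 3416 for leaf, 557 for fibrous root and 185 for tuberous root.

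Of the 5 lists called by camera, 0 were called with an estimated correlation. With probes well above background on every array 2 were called, flavonoid and starch synthesis, and the other 3 had too few members left to be tested. The antioxidant enzymes were called with normexp (adjusted p 0.00410) and with no filter (0.0419). Single lists were called or lost in 9 cases, 3 gained and 6 lost, against 127 unchanged calls. Probes higher in all 3 organs, 1152, became 621 with normexp and 168 at 4-fold, and probes lower in all 3, 870, became 428 with normexp, 555 with probes above background on both arrays and 140 at 4-fold.

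Named gene differences between 2 arrays moved by more than the spread between spots in 1277 cases, stayed within it in 1139 and, among differences of at least 2-fold, changed sign in 1: SUT2y in tuberous root was -1.44 and 0.22 with normexp. Differences under 2-fold changed sign in 68 cases, counted among the others. The spread between spots is technical, so it says nothing of plants. Organ calls of named genes held in 280 cases and were lost in 57. List medians moved in 14 cases and did not in 195. Signal over background limited the heat tuberous root array most, with 24233 probes well above background, so differences there rest on bounds more often.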

Other observations

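The values here were chosen after they were seen, and no test was run on them. Over the 18024 probes well above background on all 7 arrays, the heat tuberous root array correlated more with heat fibrous root (r = 0.872) than with ambient tuberous root (0.806). The leaf arrays correlated at 0.926 with each other, the fibrous root arrays at 0.905, and I. carnea at 0.726 with ambient fibrous root. Probes are not independent replicates.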
